A study of Mus musculus with 10 samples.

How the data were processed

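Lumbar spinal cords of female mice aged 3 months were frozen in RNAlater, and RNA was extracted with Trizol and miRNeasy columns and had integrity numbers above 8, per the labels. Stranded TruSeq libraries of polyA RNA were sequenced as read pairs over 100 cycles on a HiSeq instrument. The deposited values are whole-number read counts per gene and library, without normalisation. The submitters' processing notes name FastQC 0.11.2, Trimmomatic 0.32, STAR 2.4.2a, Picard 2.6.0, featureCounts, Subread 1.4.6, Salmon 0.8.2, DESeq2 1.14.1 and R 3.3.0, without saying which step each served, and the genome build and annotation release are not given in the sources used here. Human TARDBP has a gene identifier of its own in the table, beside a further human identifier. Gene names were taken by Ensembl identifier from a reference of the GRCm38 build (GENCODE), which named 21774 identifiers and left 250 without a name; 21336 were protein coding and 0 came from the mitochondrial genome. Coordinates are those of that reference. Whole numbers, library totals and pairwise ratios were checked on the table, and no pair of libraries was a rescaled copy (lowest chi-square per degree of freedom 4.88, over genes with at least 20 counts in a pair).

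Groups were taken from the genotype labels, and the number of the spinal cord in each title gave the replicate, called the animal number here. NTg, WT and M337V share no animal number. Per the labels, the animals numbered 1 to 3 are all M337V, 4 to 6 all NTg, and 7 to 10 M337V and WT in turn. The library names give another order. There NTg 4 to 6 are TDP_2 to TDP_4 and animals 7 to 10 are TDP_5 to TDP_8. M337V 1 to 3 are TDP_10 to TDP_12. The labels give no litter, dissection day or sequencing batch. Library totals ran from 18724888 to 21041474 counts, and floors and intervals for counts cover counting error only (3 counts for a count of 0, and 95% exact binomial intervals for shares).

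Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with low counts were removed by filterByExpr with the groups (minimum count 10, minimum total 15), which kept 15191 genes and removed 6833. Libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit, glmQLFTest) was run on a model with a mean per group over all 10 libraries. The 4 contrasts were M337V against NTg, WT against NTg, M337V against WT, and the mean of M337V and WT (weights of 0.5) against NTg. Benjamini-Hochberg adjusted p below 0.05 was the threshold, and log2 differences are given with their standard error. Group levels are the mean and SD of TMM-scaled CPM. The levels of human TARDBP, mouse Tardbp and their sum were compared by exact two-sided permutation tests, adjusted over all 9.

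Of 38 gene lists fixed in advance (pathways, cell types of the cord and its surroundings, and checks on the construct and strain), the 37 with at least 3 measured members were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted over all genes and adjusted over the list alone. A list score is the mean over its members of log2 CPM minus the gene's mean over libraries. Per comparison the genes named were up to 10 higher and 10 lower with the largest log2 difference among called genes with a mean of at least 1 CPM, up to 3 called members per fixed list and direction, up to 4 members with the smallest p of each list described, the genes around the insertion site, and, where fewer than 10 genes passed, the 10 with the smallest p. Gene models without a proper name were named only among the 3 largest changes. Genes outside this rule are marked as named after their values were seen. Some genes that met the rule are not reported here.

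Because both comparisons against NTg share their controls, their overlap was set against 20 simulated data sets without group differences. Alternatives fixed in advance were RLE size factors, no filter, a filter of 1 CPM in every group mean, a fit of the compared groups alone, limma-voom with quality weights, DESeq2 1.42.0, each library left out in turn, camera with an estimated correlation, and fry. Alternatives added after the data were seen were leaving out both NTg 4 and WT 8, robust dispersions, removal of each library's smooth trend over GC content and transcript length through offsets, the Schwann list score or the posterior Hox score as a covariate, and leaving out M337V 1 to 3 or M337V 7 and 9. A robust fit was looked at before the non-robust one that the design named.

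Each contrast was tested on simulated counts for 15191 genes with the means and totals of the real libraries, of which 200 were changed, 100 by 1.5-fold and 100 by 2-fold. For M337V against NTg 67% and 87% were recovered, with 8 false calls among 162. For WT against NTg 58% and 83% were recovered (7 false among 148), for M337V against WT 65% and 81% (10 among 156), and for the mean 81% and 87% (9 among 177). In simulated data with 1 list shifted, camera called that 1 list. Genes were drawn independently in these simulations, whereas the estimated correlation of the oligodendrocyte and myelin list in the real data was 0.46. The simulation therefore does not test the preset correlation where members of a list vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The Rosa26 transcript and raw reads were not used here, so the M337V change itself was not read from sequence.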

Results

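PolyA RNA from the lumbar spinal cord of 10 female mice aged 3 months was sequenced, and the read count of each gene was deposited as a table. Mice of the WT group (n = 2, animals 8 and 10) carried a human TARDBP gene on a bacterial artificial chromosome placed at the Rosa26 locus. TARDBP encodes TDP-43, an RNA-binding protein that regulates splicing and RNA stability. Mice of the M337V group (n = 5, animals 1, 2, 3, 7 and 9) carried the same construct with a mutation linked to amyotrophic lateral sclerosis (ALS). Nontransgenic mice formed the NTg group (n = 3, animals 4, 5 and 6), and each animal gave 1 library. Library totals were 19948913 to 21041474 counts in NTg, 19424118 to 20932246 in WT and 18724888 to 19571914 in M337V. The 15191 genes tested held 99.97% of all counts. The comparisons, their tests, the gene lists and the rule for the genes named were chosen before the data were examined.

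Reads of human TARDBP were counted under a human gene identifier (ENSG00000120948). The 7 libraries labelled transgenic held 114 to 141 CPM (counts scaled to library size) of it, with 125 ± 9.69 CPM in M337V (SD, n = 5) and 120 ± 9.29 CPM in WT (SD, n = 2). NTg 5 held 1 count (0.0493 CPM) and NTg 6 held 4 counts (0.186 CPM). The library labelled NTg animal 4 held 2415 counts (118 CPM), inside the range of the transgenic libraries, so its content went against its label. It kept its label in every comparison, and the NTg mean was therefore 39.5 ± 68.2 CPM (SD, n = 3). In exact two-sided permutation tests human TARDBP gave p = 0.0536 for M337V against NTg, where the smallest possible p was 0.0179 (0.241 adjusted over 9 tests). WT against NTg gave an exact p = 0.3, with 0.1 the smallest possible (0.643 adjusted), and M337V against WT gave an exact p = 0.619 (0.696 adjusted). Mouse Tardbp (ENSMUSG00000041459, GRCm38 chromosome 4, 148612382 to 148627019) stood at 256 ± 20.4 CPM in M337V, 249 ± 7.50 CPM in WT and 244 ± 6.20 CPM in NTg. Its exact permutation p was 0.357 for M337V against NTg, 0.5 for WT against NTg and 0.714 for M337V against WT, and edgeR gave log2 differences of 0.07 (adjusted p = 0.518), 0.03 (0.842) and 0.04 (0.932). The first of these was -0.02 after removal of trends over GC content and length (adjusted p = 0.882) and -0.01 without M337V 1 to 3 (adjusted p = 0.943). The sum of human and mouse reads was 381 ± 15.9 CPM in M337V, 370 ± 1.79 CPM in WT and 284 ± 62.2 CPM in NTg; M337V against NTg gave the smallest possible exact p, 0.0179 (0.161 adjusted). The other human gene identifier of the table had 0 counts in all 10 libraries, which allows up to 3 counts in each as far as counting error goes.

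**Figure D1:**
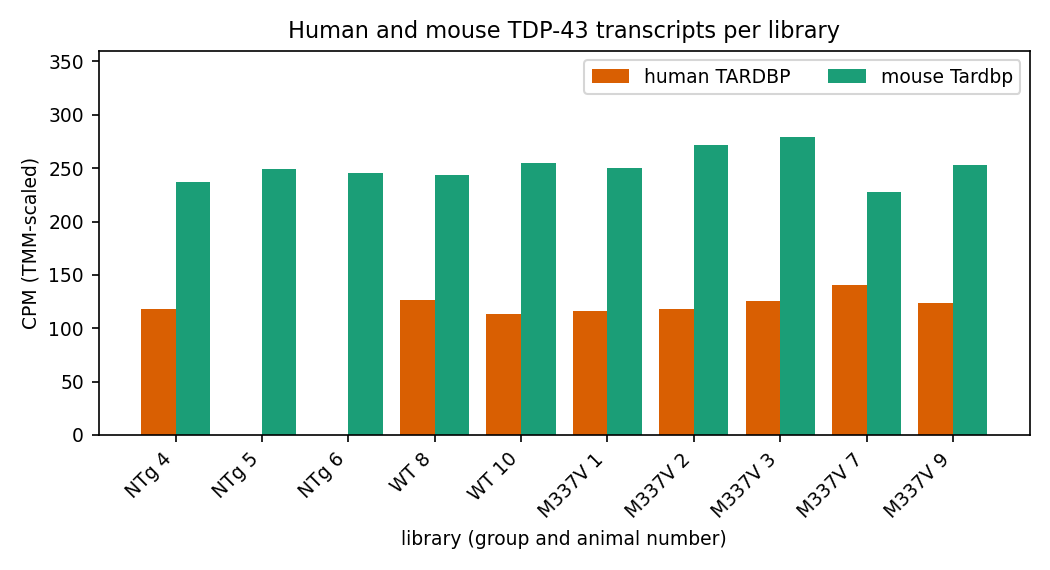
Human TARDBP and mouse Tardbp in CPM, as bars for each of the 10 libraries in their labelled groups. Human TARDBP lay between 114 and 141 CPM in the 7 transgenic libraries, at 118 CPM in the library labelled NTg animal 4, and at 0.0493 and 0.186 CPM in NTg 5 and NTg 6.

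The 3 NTg libraries lay apart from the other 7 on the first principal component, which held 28.4% of the variance. NTg 4, 5 and 6 were at 32.8, 21.6 and 29.8, and the other libraries lay between -21.2 and 4.36. The second component (21.4% of the variance) set WT 8 apart at 37.6. The libraries also differed in neighbouring tissue. The mean score of Schwann cell and nerve root markers ran from -2.18 in WT 8 to 1.55 in NTg 4. The mean score of skeletal muscle and fat genes was 1.90 in NTg 5, 2.25 in NTg 6 and 1.43 in WT 8, against 0.02 in NTg 4 and -0.11 or less in the others. Hox genes of paralog groups 10 to 13, which mark the caudal cord, had 240 counts in WT 8, 788 in M337V 3 and 2295 to 4583 in the other 8 libraries. Every M337V library (788 to 3211) lay below every NTg library (3530 to 4583), and WT 10 had 4523.

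The comparison of M337V with NTg addressed the effect of the mutant human gene, with an NTg group that included the library labelled NTg animal 4. Central myelin genes were higher in M337V cord. Ermn, which encodes the oligodendrocyte cytoskeletal protein ermin, rose from 320 ± 39.1 CPM in NTg (SD, n = 3) to 502 ± 50.9 CPM in M337V (SD, n = 5), a log2 difference of 0.65 ± 0.09 (SE, adjusted p = 0.0122). Ugt8a, which makes the myelin lipid galactosylceramide, rose from 346 ± 64.6 to 547 ± 44.1 CPM. Tspan2 (log2 0.48 ± 0.07) and Mbp, which encodes myelin basic protein (0.45 ± 0.08), also rose. Of the 26 measured genes of the oligodendrocyte and myelin list, 12 rose and 0 fell, and 21 rose when adjusted over the list alone, with a median log2 difference of 0.32. Camera with a preset correlation gave an adjusted p = 7.3e-13 for this list, and it gave adjusted p = 0.805 with an estimated correlation. The list's preset call held without any single library, the largest adjusted p being 5.2e-11 without NTg 6. Between M337V 1 to 3 and M337V 7 and 9, compared after the result was seen, its median was 0.17 (adjusted p = 1.7e-06, adjusted p = 0.697 with an estimated correlation). Its number of genes past the threshold was 8 without M337V 1, 4 without M337V 2, 7 without M337V 3, 7 without NTg 4, 0 without NTg 6, 8 after removal of GC content and length trends, and 9 without both NTg 4 and WT 8.

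P2ry12, a purinergic receptor of resting microglia, rose from 27.1 ± 3.62 CPM in NTg (SD, n = 3) to 38.8 ± 3.66 CPM in M337V (SD, n = 5; adjusted p = 0.0223), and the lysophosphatidylserine receptor gene Gpr34 (log2 0.60 ± 0.14) and the lysosomal protease gene Ctss (0.39 ± 0.08) rose with it. They were the 3 of 22 microglia genes past the threshold; 12 passed adjusted over the list alone, and the list gave an adjusted p = 2.2e-05 with the preset and adjusted p = 0.805 with an estimated correlation. Of 25 cholesterol synthesis genes 5 rose, among them Cyp51 (log2 0.35 ± 0.06), a sterol demethylase, Stard4 (0.28 ± 0.06), a sterol carrier, and Ggps1 (0.24 ± 0.06). Adjusted over the list alone 6 rose, and the list gave an adjusted p = 0.00503 (adjusted p = 0.805 with an estimated correlation). The splicing regulators Mbnl2 (log2 0.29 ± 0.06), Elavl2 (0.36 ± 0.08) and Mbnl1 (0.24 ± 0.05) rose, 3 of 43 splicing factors, or 8 higher and 1 lower adjusted over the list alone. That list gave an adjusted p = 0.00166, 0.605 after removal of GC content and length trends, and adjusted p = 0.805 with an estimated correlation. The oligodendrocyte precursor genes Vcan (0.34 ± 0.08) and Nkx2-2 (0.52 ± 0.13) rose, 2 of 17 measured (5 higher and 1 lower adjusted over the list alone), and their list gave an adjusted p = 0.0475 (adjusted p = 0.805 with an estimated correlation). Without single libraries the 5 cholesterol genes became 3 (M337V 1 or M337V 7), 1 (M337V 2, M337V 3, NTg 4 or NTg 5) or 0 (NTg 6), the 3 microglia genes 1 (M337V 3 or NTg 4) or 0 (M337V 2 or NTg 6), and the 3 splicing factors 5 (M337V 9) or 0 (M337V 2, M337V 3, NTg 4, NTg 5 or NTg 6). The precursor list's adjusted p was 0.0904 without M337V 1, 0.0614 without M337V 2, 0.0735 without M337V 7, 0.0784 without NTg 5 and 0.107 without NTg 6, and its 2 genes became 1 without M337V 1 or NTg 4 and 0 without M337V 2, M337V 3, NTg 5 or NTg 6.

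Genes tied to ALS, stress granules and targets of TDP-43 moved singly. Tmem106b (log2 0.25 ± 0.05), a lysosomal protein gene linked to frontotemporal dementia, and Chmp2b (0.25 ± 0.06), of the endosomal sorting machinery, rose among 32 ALS and frontotemporal dementia genes. Adjusted over the list alone 5 were higher and 2 lower, the median was -0.02, and the test pointed up (adjusted p = 0.927). Of 30 stress granule genes Tial1 (log2 0.32 ± 0.07), an RNA-binding protein of the granule core, and Fmr1 (0.24 ± 0.06) rose; 6 were higher and 2 lower adjusted over the list alone, and the list gave an adjusted p = 0.34. Nkain2 (0.45 ± 0.09) was the 1 of 30 transcripts of a list regulated by TDP-43 that passed, 2 adjusted over the list alone (adjusted p = 0.692 for the list). Motor neuron markers gave an adjusted p = 0.576 as a list of 23 (2 lower adjusted over the list alone), in which Mmp9 (log2 -0.88 ± 0.19), a protease of fast motor neurons, and Ache (-0.28 ± 0.05), acetylcholinesterase, fell. Mmp9 is also a gene of neutrophil granules, and it stood at 35.4, 16.5 and 20.3 CPM in NTg 4, 5 and 6 and at 12.1 to 15.2 CPM elsewhere. The neutrophil gene Ngp stood at 113, 34.5 and 56.3 CPM in NTg 4, 5 and 6. Setd5 (GRCm38 chromosome 6, 113077365 to 113153435) and Thumpd3 (chromosome 6, 113046225 to 113068273), the neighbours of the Rosa26 locus, differed by -0.02 (adjusted p = 0.845) and 0.18 (adjusted p = 0.13). The Rosa26 transcript itself was not analysed here. None of the genes of this paragraph passed without NTg 6.

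The largest decrease was in Tpm3-rs7, a retrocopy of the tropomyosin gene Tpm3, which fell from 17.9 ± 6.91 CPM in NTg (SD, n = 3) to 0.312 ± 0.146 CPM in M337V (SD, n = 5), a log2 difference of -5.81 ± 0.32 (adjusted p = 9.6e-06). Tpm3 itself, named after its values were seen, rose by 0.37 ± 0.06 (log2, adjusted p = 0.0192), and whether reads were divided between them could not be read from the counts. Myh2, a myosin of fast muscle fibres, fell from 29.8 ± 19.7 to 3.60 ± 2.69 CPM, and Mb, myoglobin, from 28.2 ± 16.8 to 4.42 ± 2.72 CPM. They were 2 of 16 muscle and fat genes (12 adjusted over the list alone; list adjusted p = 0.000717, adjusted p = 0.805 with an estimated correlation), and their levels followed the muscle score of NTg 5 and NTg 6. The neutrophil granule genes Ngp (67.8 ± 40.4 CPM in NTg, 17.2 ± 7.46 in M337V), Camp (log2 -2.01 ± 0.43) and S100a8 (-1.81 ± 0.42) fell, among 4 of 10 neutrophil and lymphocyte genes (6 adjusted over the list alone; list adjusted p = 0.01, adjusted p = 0.805 with an estimated correlation). The neutrophil score was 1.25 in NTg 4, 0.99 in NTg 6 and 0.42 in NTg 5. In M337V it ran from -0.63 to 0.52, the latter in M337V 9 and above NTg 5. The immediate early genes Dusp1 (-0.47 ± 0.10) and Klf2 (-0.99 ± 0.24) fell, 2 of 23 (5 adjusted over the list alone), with a list median of -0.49 (adjusted p = 0.000717, adjusted p = 0.805 with an estimated correlation). The immediate early score was -0.40, -0.30 and -0.28 in M337V 1 to 3 but 0.18 and 0.07 in M337V 7 and 9, against 0.31, 0.23 and 0.34 in NTg 4, 5 and 6. Between these sets of M337V animals, compared after the result was seen, the median was -0.47 (list adjusted p = 6.6e-08, adjusted p = 0.0761 with an estimated correlation). Without single libraries the muscle and fat count was 2 (M337V 7) or 0 (each of the others), the neutrophil count 1 (M337V 1) or 0 (M337V 2, M337V 3, NTg 4 or NTg 6), and the immediate early count 5 (M337V 7), 1 (NTg 4) or 0 (M337V 1, M337V 2, M337V 3, NTg 5 or NTg 6).

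In all, edgeR called 651 genes between M337V and NTg, 406 higher and 245 lower, at an adjusted p below 0.05. The median absolute log2 difference was 0.32, with 537 genes under 1.5-fold and 79 over 2-fold. The largest increases were in Ccl28, a chemokine of mucosal tissue (log2 1.21 ± 0.25), and Enpp1, an enzyme that degrades extracellular nucleotides (0.90 ± 0.13). Without both NTg 4 and WT 8 the count was 456 (288 higher and 168 lower), and 300 of the 651 were among them. The count fell to 2 without NTg 6 (Etv1, named after its values were seen, and Tpm3-rs7), to 53 without M337V 2, 161 without M337V 3, 197 without NTg 4, 280 without NTg 5, 3 without M337V 1 to 3, and 186 after removal of GC content and length trends. It rose to 1057 in a fit of both groups alone, 1146 without M337V 7 and 9, 1315 with limma-voom and 1499 with DESeq2. With the posterior Hox score as a covariate it was 953, and the median fold of the 651 was 0.999 times its main value. That score varied mostly through WT 8, which is in neither group. Its median log2 difference in Hox groups 10 to 13 was -4.24, against -0.895 to 1.46 in the other libraries. The covariate therefore does not decide whether the level of cord plays a part between M337V and NTg. Etv1, a transcription factor gene, lay between 73.3 and 82.0 CPM in the 3 NTg libraries and between 109 and 129 CPM in the other 7. All 651 genes kept their direction with DESeq2, after removal of the trends and without M337V 1 to 3, and 649 did without NTg 6. Their median fold was 0.880 times its value without M337V 1 to 3, 0.900 times without NTg 6 and 0.704 times after removal of the trends. The 651 were chosen by their calls in the main fit, and each refit shares libraries with it. Kept directions and folds were thus largely given in advance and are no independent support. Camera called 12 of 37 lists with the preset correlation, 6 up and 6 down, and 7 without M337V 1 and 3 without M337V 1 to 3. With an estimated correlation it called 0, and fry called 0. Lists of vessels, meninges and antigen presentation were among those down. Meningeal genes had a median of -0.49 (adjusted p = 0.0300, 0.165 without M337V 1, 0.150 without M337V 2 and 0.556 without NTg 4), endothelial and mural markers one of -0.19 (0.00938, and 0.0548 without M337V 1), and MHC genes one of -0.15 (0.0475, 0.214 without M337V 1, 0.150 without M337V 2 and 0.206 without NTg 4). Each gave an adjusted p = 0.914 with an estimated correlation. With the Schwann score as a covariate camera no longer called meningeal genes (adjusted p = 0.199), MHC genes (0.452) or precursor markers (0.0812), while 9 list calls held. The mean log2 difference of meningeal genes went from -0.487 to -0.227 with that covariate. Without both NTg 4 and WT 8 it was 0.00103. Without M337V 1 to 3 the calls of myelin, microglia, and muscle and fat genes remained. Those of splicing factors, precursor markers and cholesterol synthesis ended (adjusted p = 0.0691 for each), as did those of immediate early (0.132), neutrophil (0.181), MHC (0.279), meningeal (0.700) and endothelial genes (0.862), and ribosomal proteins turned (0.700). Removal of GC content and length trends ended the calls of MHC genes (0.134), ribosomal proteins (0.284) and splicing factors (0.605).

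**Figure D2:**
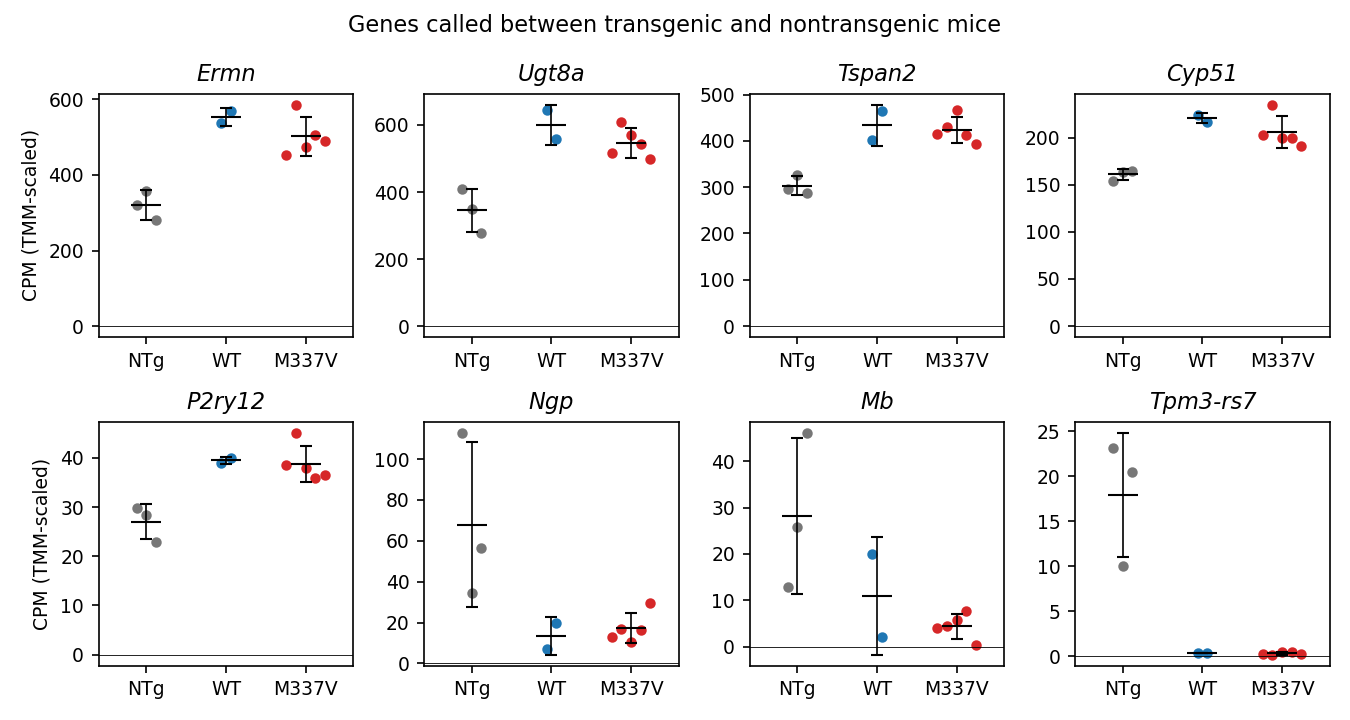
Levels in CPM, scaled by TMM, of 8 genes in each animal of the NTg (n = 3), WT (n = 2) and M337V (n = 5) groups, with the mean and SD. Ermn stood at 320 ± 39.1 CPM in NTg, 553 ± 23.1 in WT and 502 ± 50.9 in M337V, and Tpm3-rs7 at 17.9 ± 6.91, 0.327 ± 0.0191 and 0.312 ± 0.146.

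Carrying the normal human gene was addressed by the comparison of WT with NTg, again with the library labelled NTg animal 4 in the NTg group. Myelin genes were higher here too. Ermn rose from 320 ± 39.1 CPM in NTg (SD, n = 3) to 553 ± 23.1 CPM in WT (SD, n = 2), a log2 difference of 0.79 ± 0.11 (adjusted p = 0.00957). Ugt8a (0.80 ± 0.13), Gpr37 (0.41 ± 0.06), a receptor of maturing oligodendrocytes, and Enpp2 (0.49 ± 0.07), which encodes autotaxin, rose as well. Of 26 oligodendrocyte and myelin genes 12 rose and 0 fell (22 adjusted over the list alone), with a median of 0.38 and an adjusted p = 1.6e-13 (adjusted p = 0.464 with an estimated correlation). The number was 7 without NTg 4, 5 without NTg 6, 5 without WT 8 and 4 without both NTg 4 and WT 8, and the largest adjusted p of the list without a single library was 2.9e-08, without WT 8. Of 25 cholesterol synthesis genes 7 rose (13 adjusted over the list alone), including Cyp51 (0.45 ± 0.08), Stard4 (0.42 ± 0.07), Ggps1 (0.40 ± 0.07) and Insig1 (0.44 ± 0.09), the sensor protein that holds the sterol regulatory complex. That list gave an adjusted p = 2.7e-07 (adjusted p = 0.464 with an estimated correlation); 0 of its genes passed without NTg 6, 3 without WT 10 and 1 without WT 8.

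Interneuron genes were lower in WT than in NTg. Motor neuron markers were higher as a list (median 0.23; adjusted p = 0.0450, 0.146 without NTg 4, 0.0790 without NTg 5, 0.511 without WT 10, and adjusted p = 0.734 with an estimated correlation). Sst, the inhibitory neuropeptide somatostatin, fell from 71.8 ± 6.27 CPM in NTg (SD, n = 3) to 42.0 ± 4.69 CPM in WT (SD, n = 2; adjusted p = 0.0105). Penk, the enkephalin precursor (log2 -0.44 ± 0.08), Calb1, the calcium buffer calbindin (-0.48 ± 0.09), and Tac2 (-0.96 ± 0.23), a tachykinin of the dorsal horn, fell as well. They were among 6 interneuron genes that fell (13 adjusted over the list alone), with a list median of -0.25 (adjusted p = 0.000572, adjusted p = 0.464 with an estimated correlation); the number was 2 without NTg 4, 2 without NTg 6, 2 without WT 10, and 3 without WT 8. Camk2a, a kinase of excitatory synapses, fell from 208 ± 21.7 to 116 ± 10.9 CPM, while Homer1, a postsynaptic scaffold (0.32 ± 0.07), rose. Of the synaptic genes 2 rose and 3 fell (5 and 12 adjusted over the list alone; list adjusted p = 0.0856), 3 in all without NTg 4 or NTg 5 and 1 without NTg 6, WT 8 or WT 10. Hoxb9 (-0.50 ± 0.10), Hoxb8 (-0.37 ± 0.08) and Hoxb6 (-0.36 ± 0.07) fell, the 3 Hox genes past the threshold over all genes and over the list alone, and the list gave an adjusted p = 0.0557; the posterior Hox genes of WT 8 were low, as given above, and 7 Hox genes fell without WT 10, against 0 without NTg 4 or NTg 6.

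Acta2, the actin of vascular smooth muscle, fell by 1.60 ± 0.26 on the log2 scale in WT against NTg (adjusted p = 0.0117), and Myh11, its myosin, by 1.12 ± 0.29. Of 25 endothelial and mural genes 4 fell (5 adjusted over the list alone; median -0.38; list adjusted p = 4.5e-05, adjusted p = 0.7 with an estimated correlation). The number was 1 without NTg 4, 1 without NTg 5, 2 without NTg 6, 0 without WT 10 and 2 without WT 8. Col6a1, a collagen chain of fibroblasts, fell by 1.16 ± 0.30, the 1 meningeal gene past the threshold over all genes and over the list alone, and 0 passed without NTg 4 or NTg 6. The meningeal list had a median of -1.32 (camera adjusted p = 7.1e-05, adjusted p = 0.724 with an estimated correlation). With the Schwann score as a covariate its call ended (mean log2 difference -0.216, camera adjusted p = 0.912). The mean was -0.534 without both NTg 4 and WT 8, whose meningeal scores were 1.25 and -1.14. Slc4a1, the anion exchanger of erythrocytes, went from 32.3 ± 17.7 to 4.77 ± 2.83 CPM (log2 -2.75 ± 0.63), and Rhag (-3.27 ± 0.78) and Ermap (-2.63 ± 0.47), membrane proteins of erythrocytes, fell with it. The list of erythrocyte genes, which holds Slc4a1 alone of these, was not called (adjusted p = 0.0856). The Schwann cell score was 1.55 in NTg 4 and -2.18 in WT 8, and that list had a median of -1.53 (adjusted p = 0.0118, 0.0861 without NTg 4, 0.178 without WT 8, and adjusted p = 0.724 with an estimated correlation). Its mean log2 difference of -1.71 became -3.55 without WT 10 and -0.997 without NTg 4. Its 1 gene past the threshold, Mbp, rose (0.44 ± 0.10). Alb, the serum albumin gene of liver, was called higher (8.02 ± 1.70) from 36.6 CPM in WT 8, against 0.888 CPM or less in the other 9 libraries.

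For WT against NTg edgeR called 857 genes, 545 higher and 312 lower, and 142 (67 higher and 75 lower) without both NTg 4 and WT 8, of which 74 were among the 857. The count was 283 without NTg 4, 44 without NTg 6, 246 without WT 8, 265 without WT 10, 416 after removal of GC content and length trends, 515 with the Schwann score as a covariate, 258 in a fit of both groups alone, 215 with limma-voom and 1720 with DESeq2. Camera called 14 lists with the preset correlation, 5 up and 9 down, and 0 with an estimated correlation, and fry called 4. Tmem106b (0.28 ± 0.06), Chmp2b (0.32 ± 0.08) and Nkain2 (0.54 ± 0.10) rose here too, and Kcnip2 (-0.73 ± 0.19), a potassium channel subunit of the list regulated by TDP-43, fell. Setd5 differed by 0.03 (adjusted p = 0.829) and by -0.10 without WT 8, and Thumpd3 by 0.23 (adjusted p = 0.109).

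Both comparisons called 381 genes in common, 286 higher and 95 lower, with 0 in opposite directions. Ermn, Ugt8a, P2ry12, Cyp51, Tmem106b and Nkain2 were among the shared higher genes, and Tpm3-rs7, Ngp, Camp, Acta2 and Slc4a1 among the shared lower ones. Lists drawn independently would have shared 14.6 higher and 5.03 lower genes. The same 3 NTg libraries served both comparisons. A division of 3 controls would have left 1 comparison with a single control and was not made, so part of the excess may come from the shared controls. Over 14030 genes the log2 differences had a correlation across genes of 0.754, where genes are not independent replicates, and a covariance of 0.0896. In 20 simulated data sets without any group difference the shared controls alone gave a mean correlation of 0.485 (highest 0.542), a mean covariance of 0.0184 and at most 0 shared calls. Genes were drawn independently there, without factors that move many genes of a library together. The simulated range is therefore too narrow to show how much of the overlap the shared controls can give. The number in common was 107 without NTg 4, 209 without NTg 5, 2 without NTg 6 and 109 (53 higher and 56 lower) without both NTg 4 and WT 8; it was 165 with each pair of groups fitted alone, 183 with limma-voom, 933 with DESeq2 and 116 after removal of GC content and length trends.

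The mean of both transgenic groups was compared with NTg, the library labelled NTg animal 4 included, for the average effect of both constructs. A gene can pass here through either group alone, so the genes called are not all shared by both constructs. Ermn (log2 0.72 ± 0.09, adjusted p = 0.00418) and Tspan2 (0.50 ± 0.07) rose, among 17 of 26 oligodendrocyte and myelin genes (23 adjusted over the list alone; list adjusted p = 5.9e-14, adjusted p = 0.761 with an estimated correlation). Of these 7 passed without NTg 6. Of the cholesterol synthesis genes 7 rose (11 adjusted over the list alone; list adjusted p = 1.9e-05, adjusted p = 0.761 with an estimated correlation), and 1 did without NTg 6. The list of ALS and frontotemporal dementia genes was divided: Tmem106b (0.26 ± 0.05), Chmp2b (0.28 ± 0.06) and Erbb4 (0.30 ± 0.07), a neuregulin receptor, rose, and Ccnf (-0.78 ± 0.21), Anxa11 (-0.40 ± 0.11) and Dctn1 (-0.24 ± 0.06), a dynactin subunit of axonal transport, fell (list median -0.03, test up, adjusted p = 0.91). Of these, 0 passed without NTg 6, 2 higher and 0 lower without NTg 4, 2 and 2 without NTg 5, 3 and 0 without M337V 2, 3 and 1 without M337V 3, and 3 and 0 without WT 10. Acta2 (-1.23 ± 0.18) and the erythrocyte genes Ermap (-2.28 ± 0.32) and Slc4a1 (-2.21 ± 0.43) fell. Xaf1, an interferon-induced gene, rose (1.89 ± 0.49), but not in every transgenic library. It stood at 9.93 and 10.8 CPM in M337V 1 and M337V 2, against 8.19 to 10.7 CPM in NTg and 34.9 to 53.6 CPM in the other transgenic libraries. Setd5 differed by 0.00 (adjusted p = 0.972) and Thumpd3 by 0.21 (adjusted p = 0.0629).

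In that comparison edgeR called 1768 genes, 1001 higher and 767 lower, and 670 (434 higher and 236 lower) without both NTg 4 and WT 8. The count was 575 without NTg 4, 1066 without NTg 5, 98 without NTg 6, 1044 without WT 10, 739 after removal of GC content and length trends and 768 without M337V 1 to 3. Camera called 11 lists with the preset correlation, 4 up and 7 down, and 0 with an estimated correlation, and fry called 1. Among those down were endothelial and mural markers (median -0.30, adjusted p = 0.00039), meningeal genes (-0.86, 0.000867), MHC genes (-0.42, 0.000904), neutrophil and lymphocyte genes (adjusted p = 0.000965), and muscle and fat genes (-1.82, 0.00405). With an estimated correlation they gave adjusted p of 0.761, 0.839, 0.761, 0.761 and 0.776 in that order. With the Schwann score as a covariate camera no longer called meningeal genes (mean log2 difference -0.222, adjusted p = 0.578) or MHC genes (-0.104, adjusted p = 0.473). Without both NTg 4 and WT 8 the mean of the meningeal genes was -0.267.

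M337V was compared with WT to ask what the mutation adds to the human gene, and this was also the direct test of whether both effects against NTg differed. No gene passed in edgeR: 0 were called, with 1012 at an unadjusted p below 0.05, while limma-voom called 0 and DESeq2 30 (22 higher and 8 lower). 4833420G17Rik stood at 32.9 ± 2.29 CPM in M337V (SD, n = 5) and 19.8 ± 2.96 CPM in WT (SD, n = 2), a log2 difference of 0.74 ± 0.09 (adjusted p = 0.0705). Zic4, a transcription factor gene of the dorsal cord, stood at 6.70 ± 0.735 and 3.44 ± 0.245 CPM (adjusted p = 0.172). Zic1 (0.62 ± 0.10), Hoxb9 (0.56 ± 0.09), Calb1 (0.51 ± 0.09), Ccl28 (1.88 ± 0.32), Synpr (0.42 ± 0.07), Lbx1 (0.51 ± 0.09), Hoxb6 (0.37 ± 0.07) and Pcna-ps2 (-4.30 ± 0.79) had adjusted p between 0.172 and 0.237. Setd5 differed by -0.06 (adjusted p = 0.899), a sign that turned without WT 8 (0.08), and Thumpd3 by -0.05 (adjusted p = 0.915). Without both NTg 4 and WT 8 the count was 4, namely 4833420G17Rik higher and Pcna-ps2, Dsg1a and Krt2 lower. It was 1 without M337V 2 (Gdpd3), 1 without M337V 3 (Tac2), 3 without WT 8 (4833420G17Rik, Krt2 and Dsg1a), 6 without WT 10 (Alb, Apob, Ahsg, Gc, Wdsub1 and Hoxc12) and 4 without M337V 7 and 9 (4833420G17Rik, Hmgn2, Ndufs5 and Stmn1). Of the genes of these small counts, those outside the rule for named genes were named after their values were seen.

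As lists, interneuron markers and Hox genes were higher in M337V than in WT, and motor neuron markers and cholesterol synthesis genes were lower, with 0 members past the threshold over all genes in any of these lists. Interneuron markers had a median of 0.37 (10 higher and 1 lower adjusted over the list alone; list adjusted p = 5.2e-06, adjusted p = 0.355 with an estimated correlation). Motor neuron markers had a median of -0.26 (list adjusted p = 3.1e-06, 0.055 without WT 10; adjusted p = 0.706 with an estimated correlation); among them Chodl, a marker of fast motor neurons, stood at 45.1 ± 9.83 CPM in M337V and 66.7 ± 13.9 CPM in WT. The groups overlapped in both neuron scores. The motor neuron score was 0.285 in M337V 3, above 0.113 in WT 8 and 0.277 in WT 10, and -0.350 to 0.0314 in the other M337V libraries. The interneuron score was -0.127 in M337V 3, between -0.111 in WT 8 and -0.320 in WT 10, and -0.0279 to 0.160 in the other M337V libraries. M337V 3 was also the M337V library with the fewest posterior Hox counts. Cholesterol synthesis genes had a median of -0.14 (list adjusted p = 2.6e-07, adjusted p = 0.599 with an estimated correlation). Hox genes had a median of 0.13 (4 higher adjusted over the list alone; list adjusted p = 2.3e-07), and theirs was the only list call of the 4 comparisons that held with an estimated correlation (adjusted p = 0.0174); the posterior Hox genes were low in WT 8, and the list gave an adjusted p = 0.0133 without that library. WT 10, which is then the whole WT group, stood apart the other way, with the lowest median log2 difference from the other libraries in Hox groups 4 to 8 (-0.44, against -0.10 to 0.22) and the highest in groups 10 to 13 (1.46). The call could therefore not be separated from the level of cord that each WT library held. Camera called 16 lists here with the preset correlation, 11 up and 5 down. Schwann cell markers had a median of 1.11 (list adjusted p = 1.2e-05, 0.0881 without WT 8; adjusted p = 0.706 with an estimated correlation), and their mean log2 difference of 1.36 became 3.20 without WT 10 and 0.948 at the lowest, without M337V 3.

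**Figure D3:**
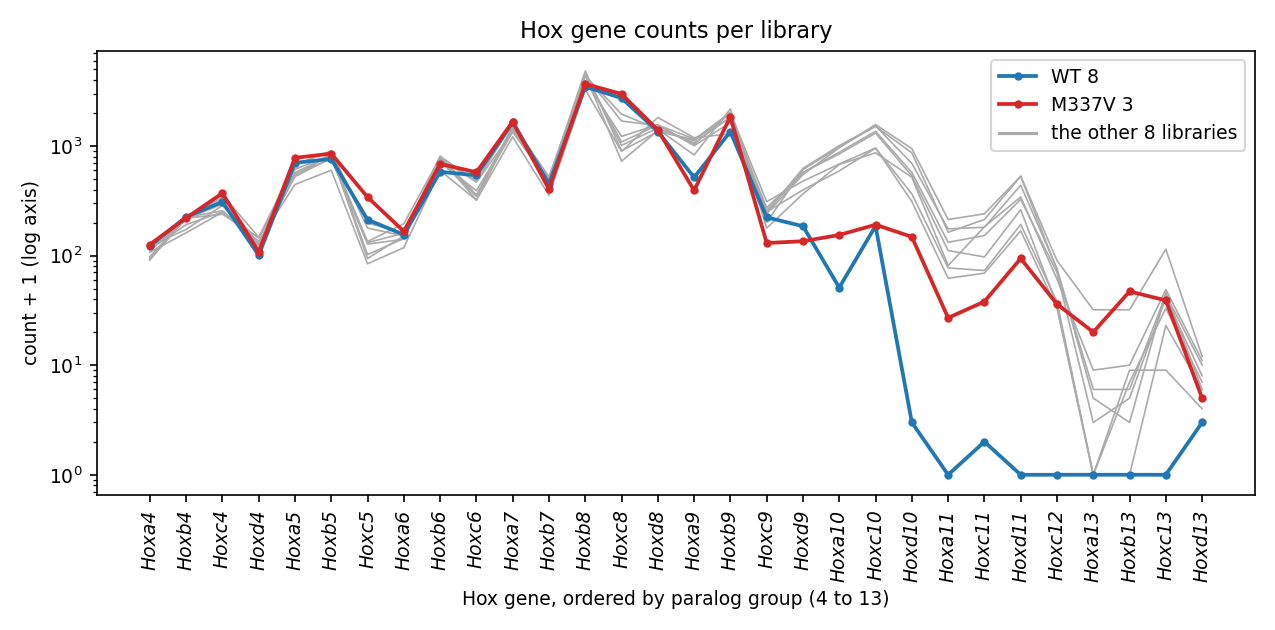
Read counts plus 1, on a log axis, of Hox genes in order of paralog group from 4 to 13, with 1 line per library. WT 8 is drawn in blue, M337V 3 in red and the other 8 libraries in grey; summed over groups 10 to 13, WT 8 had 240 counts, M337V 3 had 788 and the others had 2295 to 4583.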

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

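The tests of animal numbers, of human TARDBP in NTg 4 and of the Hox genes of WT 8 were chosen after the results were seen, and so were the alternatives that removed trends over GC content and length, used the Schwann score as a covariate or left libraries out in sets.

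The first pattern was the 651 genes called between M337V and NTg, the library labelled NTg animal 4 included. Of the 56 splits of the 8 libraries only 1, the real one, called as many, which argued against chance. Chance was not excluded, because 1 of 56 is the smallest share the test can give. The highest other, 267, set M337V 1, 2 and 3 against the rest, so a grouping other than the genotype also called genes. Different amounts of nerve root were tested with the Schwann score as a covariate, and a fall of the folds was predicted for this cause. The median fold of the called genes was 1.03 times its value without the covariate. These genes were chosen in a fit of the same libraries, where a gene that varies with nerve root within groups is less likely to pass. The ratio was thus largely given in advance and does not decide on nerve root. With this covariate the calls of the meningeal, MHC and precursor lists ended. Bias over GC content and transcript length may account for part of the pattern: with those trends removed 186 genes were called. The median absolute log2 difference of the 651 went from 0.32 (quartiles 0.26 to 0.45) to 0.23 (0.15 to 0.37), while their standard errors were 0.910 times as large. Calls thus ended because the differences shrank. All 651 kept their direction, which says little, since they were chosen in a fit of the same libraries. A difference between runs of animal numbers and the genotype cannot be told apart, because animals 4 to 6 are all NTg. No run of title numbers holds both M337V and NTg. In the order of the library names NTg 4 to 6 (TDP_2 to TDP_4) come directly before M337V 7 (TDP_5), and M337V 1 to 3 (TDP_10 to TDP_12) come last. The labels do not say whether either order follows the handling of the animals. The 22 genes called between M337V 1 to 3 and M337V 7 and 9, 0 of them among the 651, were fewer than the bound written for this test. That bound compares runs of M337V and does not bear on the NTg libraries, and an effect of the transgene stays open beside it.

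The second pattern was human TARDBP in the library labelled NTg animal 4, at 118.3 CPM. Reads carried over from other libraries were argued against, since its level was 0.957 of the mean of the 7 transgenic libraries, while NTg 5 and NTg 6 had 1 and 4 counts. A swap with a transgenic library of the series was argued against, since the lowest of these stood at 0.921 of their mean and none lacked the human reads. The level lies within the 114 to 141 CPM of the transgenic libraries and is consistent with tissue of a transgene-carrying animal under the NTg label, a hypothesis from the same values it would explain. Mouse genes ran with the label, since the library lay at 32.8 on the first principal component, beside 21.6 and 29.8 for NTg 5 and NTg 6 and at most 4.36 for the transgenic libraries, and held 23.1 CPM of Tpm3-rs7 against 0.470 CPM or less in these, so the explanation stays open.

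The third pattern was the low posterior Hox counts of the library labelled WT animal 8, 240 over paralog groups 10 to 13. Low depth was argued against by its total of 19424118 counts, within the range of the others. In groups 10 to 13 the median log2 difference from the other libraries was -4.24 over 11 genes (quartiles -5.47 to -2.28), and in groups 4 to 8 it was 0.15 over 15 genes (quartiles -0.05 to 0.30). Tissue from a more rostral level of the cord may account for this, as a hypothesis. Whether genotype alters posterior Hox genes was not tested apart from it, and WT 10 had 4523 counts.

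For the mean of both transgenic groups against NTg, 1 of 100 drawn splits called as many as the real 1768, itself the real one. The highest other called 71, which argued against chance. Chance was not excluded, because 1 of 100 is the smallest share these draws can give.

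Among the 5 M337V libraries, 9 of 141 values had 1 library whose gap to the nearest other was more than 0.71 of the group's range, Dixon's critical value, which chance gives in about 1 of 20 groups. The total of M337V 2, 18724888 counts, lay below 19343261 to 19571914 (gap share 0.730). M337V 9 had the highest erythrocyte score, 1.43 against -0.59 to -0.07 (0.744). M337V 3 had the lowest circadian score, -0.12 against -0.02 to 0.00 (0.860). Mb was low in M337V 9, at a log2 CPM of -1.47 against 2.07 to 2.96 (0.798). Sst was low in M337V 3, 5.59 against 5.86 to 5.95 (0.753), as was Tac2, 4.05 against 4.84 to 5.04 (0.799). Zic4 was low in M337V 9, 2.47 against 2.78 to 2.88 (0.748). Wdfy1, a gene that differs between mouse substrains, was high in M337V 7, 6.28 against 5.63 to 5.66 (0.955). S100b, a calcium-binding protein of astrocytes, was high in M337V 2, 10.10 against 9.86 to 9.91 (0.795).

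The comparison of M337V with WT, which tests the difference between both effects against NTg, called 16 lists by camera with the preset correlation. Median log2 differences were higher in M337V for cytosolic ribosomal proteins (0.11), Hox genes (0.13), interneuron markers (0.37), Schwann cell markers (1.11), meningeal genes (0.83), MHC genes (0.25), endothelial markers (0.19), erythrocyte genes (1.07), neutrophil and lymphocyte genes (0.52), microglia markers (0.0916) and reactive astrocyte genes (0.15). They were lower for cholesterol synthesis (-0.14), motor neuron markers (-0.26), oligodendrocyte and myelin genes (-0.10), heat shock genes (-0.0621) and axonal genes (-0.0686). The mean log2 difference of meningeal genes (0.826) ran from 0.522 without M337V 7 to 1.41 without WT 10, and that of Schwann cell markers (1.36) from 0.948 without M337V 3 to 3.20 without WT 10. With an estimated correlation Hox genes had an adjusted p = 0.0174 and the other 15 had 0.355 or more. Without WT 8 the adjusted p was 0.0512 for ribosomal proteins, where camera's direction relative to other genes turned while their mean log2 difference stayed positive (0.0172), 0.0881 for Schwann cell markers, 0.0889 for reactive astrocyte genes, 0.0957 for axonal genes, 0.119 for MHC genes, 0.233 for meningeal genes, 0.308 for oligodendrocyte genes and 0.96 for neutrophil and lymphocyte genes. Without WT 10 it was 0.055 for motor neuron markers, 0.136 for erythrocyte genes, 0.166 for axonal genes, 0.205 for endothelial markers, 0.297 for reactive astrocyte genes, 0.736 for microglia markers and 0.994 for heat shock genes, where that relative direction turned while the mean log2 difference stayed negative (-0.0221). Single M337V libraries ended the calls of microglia markers (0.0819 without M337V 1, 0.139 without M337V 2, 0.0855 without M337V 7), axonal genes (0.0763 without M337V 2), heat shock genes (0.0626 without M337V 7), neutrophil and lymphocyte genes (0.0972 without M337V 9) and reactive astrocyte genes (0.0515 without M337V 3, 0.297 without M337V 7). Without M337V 7 and 9 the calls ended for axonal genes (0.0652), MHC genes (0.0773), microglia markers (0.102), neutrophil and lymphocyte genes (0.254), endothelial markers (0.276), reactive astrocyte genes (0.303) and oligodendrocyte genes (0.511). With the Schwann score as a covariate they ended for erythrocyte genes (0.0701), axonal genes and endothelial markers (0.0743 each), oligodendrocyte genes (0.155), neutrophil and lymphocyte genes (0.478), MHC genes (0.829) and reactive astrocyte genes (0.886), and turned for Schwann cell markers (0.284) and meningeal genes (0.293). The calls of interneuron markers, motor neuron markers, cholesterol synthesis and Hox genes held in both.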

How the results depend on the processing

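The fits without both NTg 4 and WT 8, with robust dispersions, with trends over GC content and length removed, with the Schwann or posterior Hox score as a covariate, and without M337V 1 to 3 or M337V 7 and 9 were chosen after the data were seen. No paired analysis was possible because the groups share no animal numbers. Over all named genes and alternatives, 3301 results kept their direction and their side of the threshold, 1399 no longer passed, 19 newly passed and 21 turned; over the lists, 790 kept both, 129 no longer passed and 13 turned. The counts depend on single libraries of every group, and leaving libraries out also leaves fewer to estimate the spread. A fit chosen after the data were seen kept all 10 libraries, with M337V 1 to 3 and M337V 7 and 9 as separate groups. There M337V 1 to 3 differed from NTg at 1510 genes and M337V 7 and 9 at 3, with 2 in both. The low count without M337V 1 to 3 thus did not need fewer libraries for the spread, although the group compared was also smaller. After removal of GC content and length trends the differences themselves shrank. For the other settings the cause was not tested. Where WT is left with 1 library, that library is assumed to vary like the other groups.

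Leaving out 1 library at a time gave 2 (without NTg 6) to 723 (without M337V 7) genes for M337V against NTg, 44 (without NTg 6) to 576 (without NTg 5) for WT against NTg, 0 to 6 (without WT 10) for M337V against WT, 98 (without NTg 6) to 1840 (without WT 8) for the transgenic mean, and 2 (without NTg 6) to 209 (without NTg 5) genes in common. It gave 7 to 14, 10 to 14, 12 to 18 and 11 to 15 list calls in that order, and 0.05 to 0.12 for the log2 difference of Tardbp between M337V and NTg. For M337V against NTg the compared groups alone gave 1057 genes, limma-voom 1315, DESeq2 1499, the GC content and length correction 186, M337V 1 to 3 left out 3 and M337V 7 and 9 left out 1146. The 3 were Tpm3-rs7 and Hnrnpa0, lower, and Xaf1, higher, of which Hnrnpa0 was named after its values were seen. For WT against NTg the compared groups alone gave 258, limma-voom 215, DESeq2 1720, both NTg 4 and WT 8 left out 142, the correction 416 and the Schwann covariate 515. Of the calls for WT against NTg, 176 of 215 were higher with limma-voom, 545 of 857 in the chosen fit and 67 of 142 without NTg 4 and WT 8. For M337V against WT no filter gave 1, robust dispersions 1 and the Hox covariate 1 (4833420G17Rik in each), DESeq2 30, NTg 4 and WT 8 left out 4 and M337V 7 and 9 left out 4, against 0. For the transgenic mean, leaving out NTg 4 and WT 8 gave 670, the correction 739 and leaving out M337V 1 to 3 gave 768. The genes in common were 165 with compared groups alone, 183 with limma-voom, 933 with DESeq2, 109 without NTg 4 and WT 8, and 116 with the correction.

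List calls for M337V against NTg were 3 without M337V 1 to 3, 0 with an estimated correlation and 0 with fry, against 12. For WT against NTg they were 0 with an estimated correlation and 4 with fry, for the transgenic mean 0 and 1, and for M337V against WT 1 and 1, with 9 under the Schwann covariate. Mean log2 differences of lists whose test turned were, for cytosolic ribosomal proteins, -0.0405 in M337V against NTg without M337V 1 to 3, -0.00144 in WT against NTg without NTg 4 and WT 8, -0.0413 with the Schwann covariate, -0.0429 with the Hox covariate (range without single libraries -0.223 to 0.00583, the latter without WT 8), and 0.0163 in M337V against WT without NTg 4 and WT 8 (range 0.0172, without WT 8, to 0.246). With the Schwann covariate Schwann cell markers turned to 0.0600 in WT against NTg and -0.056 in M337V against WT, and meningeal genes to -0.0105 in M337V against WT (the covariate is the mean of the Schwann list itself). Splicing factors turned to -0.00500 in the transgenic mean with the correction. Without single libraries, skeletal muscle and fat genes in WT against NTg ran from -3.74 to -0.35 (without WT 10, where the test turned), and heat shock genes in M337V against WT from -0.23 to -0.0221 (without WT 10, likewise).

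Tardbp, which passed in no fit, turned to -0.0249 with the correction and -0.0142 without M337V 1 to 3 for M337V against NTg, -0.107 with the correction for WT against NTg, -0.066 with it for the transgenic mean, and -0.059 without M337V 1 to 3 for M337V against WT. Setd5, which passed in no fit either, turned to 0.00957 with the correction for M337V against NTg. For WT against NTg it was -0.117 without NTg 4 and WT 8, -0.111 with the Schwann and -0.072 with the Hox covariate (-0.105 to 0.16 without single libraries). For M337V against WT it was 0.0794, 0.0578 and 0.0118 in that order (-0.185 to 0.0802), and for the transgenic mean -0.0774, -0.0822 and -0.0661, and -0.00536 with limma-voom (-0.0648 to 0.0676).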

Other observations

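The test that placed NTg 4 on an axis between NTg and M337V was chosen after the result was seen, as were the comparison of M337V 1 to 3 with M337V 7 and 9 and the genes marked so.

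Single clock genes differed between M337V and NTg, the library labelled NTg animal 4 included. The repressors Per2 (log2 -0.60 ± 0.10, adjusted p = 0.0189) and Per1 (-0.76 ± 0.18) fell, and the activators Clock (0.24 ± 0.04) and Rora (0.24 ± 0.04) rose, 4 of 20 measured (3 higher and 4 lower adjusted over the list alone). Camera of limma found no shift of the list one way (adjusted p = 0.637). The number was 0 without M337V 2, 0 without NTg 6 and 2 without NTg 5. Rora (0.30 ± 0.05), Clock (0.26 ± 0.05) and Nr1d2 (0.28 ± 0.07) rose in WT against NTg; the number was 1 without NTg 4 or WT 10, 0 without NTg 6, and 1 higher and 1 lower without WT 8. The time of day of dissection is not given in the labels. Ddit4, induced by stress and glucocorticoids (-0.63 ± 0.12), also fell in M337V. Synaptic genes split in the transgenic mean against NTg: Homer1 (0.24 ± 0.05) rose, while Camk2a (-0.59 ± 0.09), Nlgn2 (-0.26 ± 0.06), a protein of inhibitory synapses, and Grin1 (-0.31 ± 0.08), an NMDA receptor subunit, were among 7 of 35 that fell (4 higher and 15 lower adjusted over the list alone; list adjusted p = 0.137). In all 9 passed, and 3 without NTg 4, 5 without NTg 5, 1 without NTg 6, 3 without WT 10 and 14 without WT 8.

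Some genes followed the runs of animal numbers or differed among M337V animals, in genes named after their values were seen. Between M337V 1 to 3 and M337V 7 and 9 edgeR called 22 genes, 12 higher and 10 lower in the former. Hmgn2, a nucleosome-binding protein, stood at 22.7 to 25.9 CPM in M337V 1 to 3, at 58.2 and 61.3 CPM in M337V 7 and 9, at 61.1 and 65.3 CPM in WT 8 and WT 10, and at 39.3 to 53.2 CPM in NTg (log2 -1.31 ± 0.11, adjusted p = 0.00282). Reln, the matrix protein reelin (-1.24 ± 0.15), Kit (-0.76 ± 0.08) and Stmn1, a regulator of microtubules (-0.58 ± 0.06), were lower in M337V 1 to 3 than in M337V 7 and 9, and Hnrnpa0, an RNA-binding protein, was higher (0.53 ± 0.05). Stmn1 stood at 142 to 155 CPM in animals 1 to 3, 163 to 185 CPM in animals 4 to 6 and 222 to 234 CPM in animals 7 to 10. Stmn1 and Hmgn2 thus rose with the numbers of the titles across groups. In the order of the library names animals 1 to 3, the lowest, come last (TDP_10 to TDP_12), so neither gene rose steadily with that order. A few genes were high in some animals and low in others within a group. Xaf1 stood at 8.19 to 10.8 CPM in the 3 NTg libraries, M337V 1 and M337V 2, and at 34.9 to 53.6 CPM in the other 5. Wdfy1 stood at 68.7 to 79.0 CPM in NTg and M337V 7 and at 47.4 to 50.5 CPM in the other 6. Pcna-ps2 stood at 2.42 to 3.20 CPM in NTg 5, NTg 6, WT 8 and WT 10 and at 0.256 CPM or less in the others. Gdpd3 stood at 4.98 to 12.9 CPM in the NTg and WT libraries and M337V 2, and at 0.572 to 1.15 CPM in M337V 1, 3, 7 and 9.

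Traces of other tissue appeared in single WT libraries, in genes named after their values were seen. The liver genes Alb (36.6 CPM), Apob (2.88 CPM), Ahsg (2.41 CPM) and Gc (2.35 CPM) stood highest in WT 8, where the other libraries held at most 0.888, 0.103, 0.157 and 0.157 CPM. The skin genes Krt2 (17.5 CPM) and Dsg1a (2.39 CPM) stood highest in WT 10, against at most 0.196 and 0.0517 CPM elsewhere.

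Alleles of another strain linked to the Rosa26 locus were tested as a source of the genes called between M337V and NTg. Within 20 Mb of the locus 5 of 228 tested genes were called (2.19%, exact binomial 95% interval 0.716 to 5.04%), against 643 of 14921 elsewhere (4.31%), a ratio of 0.509 (Fisher's exact p = 0.137). No excess near the locus was seen, which argues against such alleles as a source of extra calls among the 228 genes there. So few genes could directly make up only a small part of the pattern. The test did not cover alleles elsewhere in the genome, or effects of linked alleles on distant genes. NTg 4, which held human TARDBP, was also counted as NTg here.

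Expression of the human gene as the whole cause of the difference between M337V and NTg was tested on NTg 4, which holds human TARDBP. On an axis from NTg (0) to M337V (1), set by 200 genes from a fit without the library placed, NTg 4 lay at a median of 0.317 (quartiles 0.142 to 0.539), beside 0.368 for NTg 5 and -0.15 for NTg 6. Held-out transgenic libraries lay from 0.723 (M337V 1) upwards, with WT 8 at 1.13 and WT 10 slightly above it. The library was thus nearer to NTg than to the transgenic animals in mouse genes, although 1 library cannot exclude the transgene as the cause, which may remain part of it.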
